A study of Arabidopsis thaliana with 35 samples.

How the data were processed

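Seedlings of Arabidopsis thaliana Col-0 with a functional FRI allele were grown at 22 °C with 16 h of light and sampled without cold, in the cold, or after cold and a return to normal growth, per the labels. RNA was sequenced without cold (NV), after 1 h, 1 d, 10 d, 20 d and 40 d of cold, and after 40 d of cold followed by 10 d of normal growth (T10), with 2 replicates per group. Chromatin immunoprecipitation with sequencing (ChIP-seq) covered H3K27me3, H3K4me3 and H3K36me3 at NV, 40 d of cold and T10, with 2 replicates per mark and time point, beside 3 input libraries. The input libraries entered only through the peak calls made against them and were not used here otherwise.

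The RNA values are a signal: the authors deposited normalised read counts averaged over the 2 replicates of a group, in 1 table of 7 columns. Total RNA was depleted of ribosomal RNA and made into libraries with a stranded kit, per the labels. TopHat and edgeR are named in the submitters' processing notes, with the genome build TAIR10 and without versions or settings. The values are not divided by gene length, and the deposited column sums differ (0.823 to 1.49 M, where M is 1e+06) while the medians are alike (6.01 to 6.33). Of 18779 listed genes, 18610 (99.1%) matched the RefSeq gene table of the assembly TAIR10.1 by identifier; the 157 identifiers of organelle genes, taken from the identifiers themselves, did not.

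Per the file headers, the authors called peaks with MACS 2.1.1.20160309 in each ChIP library alone against the input of the same time point. The headers give no shifting model, tags extended to 600 bp, narrow peaks, a q-value limit of 5.00e-02, an effective genome of 1.00e+08 bp and 1 tag kept per position. Bowtie2 is named in the submitters' processing notes. The deposited peak files hold 1-based start, end and length in bp, the pileup signal at the summit, the fold enrichment as a ratio over the local background, and the p-value and q-value as −log10. Only the positions and the −log10 q were used to compute calls here, and pileup was not used here.

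The choices of samples, comparisons, calls, alternatives and gene lists were made before the data were examined. Genes were called higher or lower by size alone: at least 2-fold on log2(value + 1), with the higher group mean at 1 or more. Each cold time and T10 were compared with NV, and T10 with 40 d of cold. Fixed lists of genes were described by their median log2 ratio, placed among 10000 random lists of the same size matched on mean expression in 10 classes. RNA counts for a list cover only members in the deposited table, such as 8 of 19 for floral promotion and 12 of 20 for heat shock. Persistence was the number of genes called at 40 d and again, in the same direction, at T10.

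A test for RNA was added after seeing the data. Each averaged value proved to be the sum of whole multiples of 2 column-specific steps, 1 per averaged library. Between 99.95% and 99.98% of the values of a column had exactly 1 whole-read solution at a relative tolerance of 1e-12. Splitting the values gave reads for 14 libraries, named here the deeper and the shallower library of a group, since the table carries no replicate numbers. Tested on simulated data, 99.973% of values had 1 solution, and 100% of those equalled the simulated reads. Reads in uniquely split genes ran from 2.38 M (T10, shallower) to 19.9 M (40 d of cold, deeper). The effective library sizes behind the authors' scaling ran from 5.77 to 51.5 M. Genes with a value that could not be split uniquely, 13 in all and 3 of them nuclear, were left out of this test. limma 3.58.1 with voom was fitted to all 14 libraries, which share 1 estimate of the spread. A gene "rose" or "fell" where its Benjamini-Hochberg adjusted p was under 0.05 over 18766 genes. Fitted log2 changes are given with their standard errors (SE). In a simulation of 40 d of cold against NV, 200 of the 18766 genes were changed. The fit found 41% of the 2-fold and 100% of the 4-fold changes, and 2.08% of its calls were false. That simulation gave every library the same dispersion (spread beyond counting error). In the data it was estimated at 0.0658 in NV and 0.108 at 1 h, but 0.00308 at 1 d and 0.00817 at 40 d. How many calls are false when groups differ in spread was therefore not measured.

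For ChIP-seq, peaks were laid over 27444 protein-coding nuclear genes of the RefSeq table. A gene was marked in a library where peaks covered at least 50% of its feature. The feature was the gene body for H3K27me3 and H3K36me3. For H3K4me3 the planned feature, 1000 bp from the 5′ end, could not be drawn because the table holds no strand. The covered length over the gene divided by 1000 bp (or by the gene length if shorter), at most 1, replaced it. As the table's assembly carries another name than the build of the files, the frames were checked with the H3K36me3 peaks of NV. Over 34 windows of 3 Mb, the shift with the highest overlap of these peaks and expressed genes lay between −100 and 100 bp. No coordinates of that table are printed.

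A gene gained a mark if marked in both libraries of the later group and neither of the earlier, and lost it the other way round. Each count stands beside the same count for the other two splits of the 4 libraries into pairs: replicates 1 against replicates 2, and the crossed pairs. limma was also fitted to the covered share over the 6 libraries of a mark, for genes whose share varied by at least 0.1, with an adjusted p under 0.05 and a mean difference of at least 0.25. In a simulation of H3K4me3 at 40 d of cold against NV, with 200 of 5183 genes raised by 0.5, 43% were found and 7.53% of calls were false. ChIP depth after removal of duplicate tags ran from 3.42 to 37.0 M tags, per the file headers. The files of replicates 1 and 2 were processed under different naming and differ in duplicate tags, so counts within each replicate number are given beside the pooled ones.

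RNA medians of genes that gained or lost a mark were placed among 10000 random sets matched on expression. Overlaps between marks were tested with Fisher's exact test, two-sided, over 36 pairs of sets among the 27444 protein-coding genes. The plan named only genes that could have been called for both marks. Counting genes never marked as well lowers the overlaps expected of independent sets. Peak numbers and covered lengths were compared with exact two-sided permutation tests, whose smallest possible p with 2 libraries against 2 is 0.33.

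Genes are named in the text under a fixed rule. (1) RNA: the 12 largest positive and 12 largest negative log2 ratios among called genes for the main comparisons, 6 and 6 for the shorter times, without organelle, rRNA, tRNA, snRNA and snoRNA genes. (2) ChIP-seq: the 6 gained and 6 lost genes with the largest difference in covered bp. (3) Genes called in RNA that also gained or lost H3K27me3, the 5 largest in each direction. (4) Members of 23 fixed lists with 334 members: FLC clade, floral promotion, other floral repressors, VIN3 family and VRN genes, Polycomb, demethylases and methyltransferases, FRI complex, autonomous pathway, cold acclimation, sugar and proline, circadian clock, light harvesting and Rubisco, flavonoid, heat shock, gibberellin, salicylic acid, jasmonate, floral organ identity, meristem, cell cycle, senescence, root markers and reference genes. Where many genes meet the rule, those named are the ones at its top or the best known, and the rest are counted.

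Alternatives for RNA calls by size were pseudocounts of 0.1 and 5 in place of 1, no floor, a floor 5 times higher, and median-ratio scaling over 14519 nuclear genes. For the RNA test they were limma-trend on log2(value + 1), a filter at 1 RPM (reads per M) in at least 2 libraries, and each library left out. For ChIP-seq they were any overlap of 1 bp, a covered share of 0.8, peaks with −log10 q of at least 10, the same covered length in each library of a mark (its strongest peaks), each replicate left out, the replicate number as a block in limma, and regions merged from all peaks without genes. The RNA test with its alternatives, the merged regions, and the equal covered length for the RNA of marked genes were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3. Intervals given for genes with few reads are 95% and cover counting error only, since the reads carry no molecular identifiers.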

Results

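RNA-seq covered 7 groups of seedlings with 2 libraries each: without cold (NV), after 1 h, 1 d, 10 d, 20 d and 40 d of cold, and 10 d after the return from 40 d of cold (T10). ChIP-seq of H3K27me3, H3K4me3 and H3K36me3 covered NV, 40 d of cold and T10, also with 2 libraries each. The RNA table lists 18779 genes, and reads in uniquely split genes ran from 2.38 to 19.9 M per library, where M is 1e+06. Across genes, which are not independent replicates, the libraries of a group correlated at r 0.925 (1 h) to 0.992 (1 d and 10 d). NV and 1 h libraries did not sort by group: the deeper NV library correlated with the shallower 1 h library at 0.973 and the shallower NV with the deeper 1 h library at 0.97, above the 0.952 within NV. ChIP libraries held 3.42 to 15.6 M filtered tags for H3K27me3, 20.1 to 37.0 M for H3K4me3 and 8.49 to 23.3 M for H3K36me3. For each gene said to have risen or fallen, both libraries of the later group lay on the same side of both libraries of the earlier group. Expression values are mean normalised counts per group. The question behind the comparisons is which transcripts and marks change during vernalization and which of those changes last after warmth returns. NV is the only group without cold, and no second such group stands beside 40 d or T10. Differences from NV can therefore include those of age and development, which cannot be told apart from cold here.

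After 40 d of cold, the floral repressor FLC (AT5G10140) had fallen and the floral integrator SOC1 (AT2G45660) and the vernalization gene VIN3 (AT5G57380) had risen. The cold-regulated genes COR15A (AT2G42540), KIN1 (AT5G15960) and RD29A (AT5G52310) were among the largest rises. DIN10 (AT5G20250) and DR4 (AT1G73330) were among the largest falls, and 10 of 15 flavonoid genes and 8 of 14 root markers fell. FLC went from 17.3 to 8.38 (log2 change −1.05, SE 0.18, limma with Benjamini-Hochberg adjusted p 0.000909). SOC1 went from 0.259 to 9.34 (log2 change 5.89, SE 0.86, adjusted p 0.00034). VIN3 had 2 and 0 reads in the NV libraries and 162 and 243 after 40 d, a ratio of 167 with a 95% counting interval from 45.9 to 1383 (adjusted p 0.00282).

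**Figure D1:**
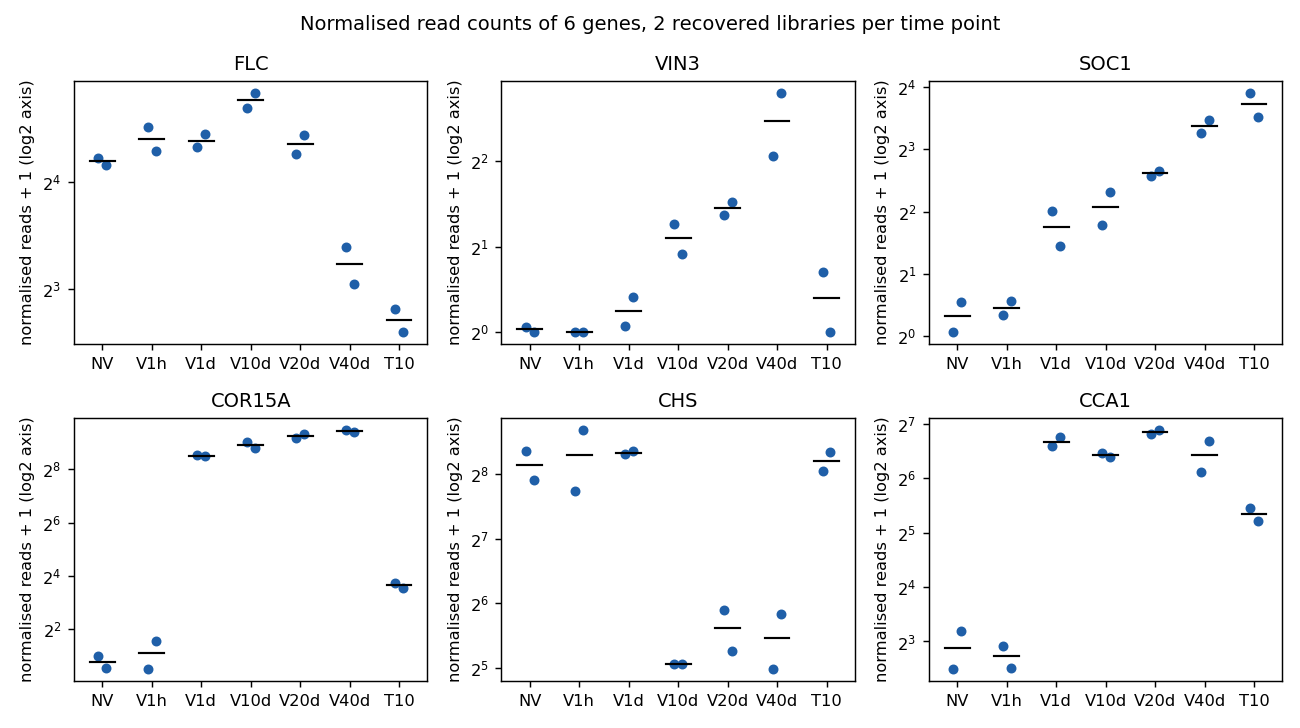
Expression of 6 genes over the 7 groups, in reads per M plus 1 on a log2 axis. Dots are the 2 recovered libraries of a group, bars their mean.

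COR15A rose from 0.705 to 699 (log2 change 9.98, SE 0.47, adjusted p 2.48e-07) and KIN1 from 1.08 to 349 (8.71, SE 0.54, adjusted p 1.06e-06). Also among the 12 largest rises were COR15B (AT2G42530), RD29A, COR27 (AT5G42900), the galactinol synthase GOLS3 (AT1G09350), alcohol dehydrogenase ADH1 (AT1G77120), COR413IM1 (AT1G29395), the defensin PDF2.1 (AT2G02120), protochlorophyllide reductase PORA (AT5G54190) and PYD4 (AT3G08860). How reads were shared between the close paralogs COR15A and COR15B, or KIN1 and KIN2, was not checked here. DIN10 fell from 622 to 6.32 (log2 change −6.58, SE 0.30, adjusted p 2.3e-07) and DR4 from 117 to 0.885 (−7.02, SE 0.53, adjusted p 3.29e-06). GDPD2 (AT5G41080), CYP705A5 (AT5G47990), the aquaporin TIP2;2 (AT4G17340), PCK2 (AT5G65690) and XTH18 (AT4G30280) fell by 5.75 to 7.56 on the log2 scale. MSRB6 (AT4G04840) had 2 reads left after 40 d, a ratio of 0.000439 (5.31e-05 to 0.00159), and SDR4 (AT3G29250) also 2, a ratio of 0.000781 (9.46e-05 to 0.00283).

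In all, limma called 3093 genes up and 3440 down of 18766 after 40 d. By size alone, 1120 genes were at least 2-fold higher and 1754 lower. The rises numbered 1909 without the deeper NV library, 1936 without the deeper and 1878 without the shallower 40 d library. The falls numbered 1865 and 1953 without the deeper and the shallower 40 d library. Of 167 called genes that belong to a fixed list or to the named genes, 98 kept the call whichever library of either group was left out. The genes named here for this comparison are among those 98 unless values without a library stand beside them.

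Among flowering genes, MAF3 (AT5G65060) rose with a log2 change of 0.87 (SE 0.19, adjusted p 0.00485) while FLC fell. MAF2 (AT5G65050) rose too (0.80, limma adjusted p 0.0258), but not without the deeper NV library (0.207) or either 40 d library (0.0791 and 0.101). In the FLC clade as a whole, 2 genes rose and 1 fell of 5 measured (2 and 1 adjusted over the list alone). Of 8 measured floral promotion genes 4 rose, SOC1, GI (AT1G22770), FD (AT4G35900) and AGL24 (AT4G24540) (5 adjusted over the list alone). The calls of FD and AGL24 were lost without the deeper NV library (0.254 and 0.283) or either 40 d library (0.0756 to 0.121), and that of AGL24 also without the shallower NV library (0.0848). Of 8 other floral repressors, SVP (AT2G22540) rose by log2 1.08, SNZ (AT2G39250) by 1.67 and SMZ (AT3G54990) also rose, while 2 fell (4 and 3 adjusted over the list alone). Of these falls 1 was left without the deeper NV or the shallower 40 d library and none without the deeper 40 d library. VIN3 was the only gene called of 5 in the VIN3 family and VRN list (1 and 0 adjusted over the list alone; 2 rises without the shallower NV library).

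Among genes for histone modification, the Polycomb methyltransferase genes CLF (AT2G23380) and SWN (AT4G02020) rose by log2 1.84 (SE 0.26, limma adjusted p 0.000275) and 1.28 (SE 0.25, adjusted p 0.00236), the 2 calls among 9 Polycomb genes (2 and 0 adjusted over the list alone). JMJ30 (AT3G20810) rose by 3.63 (SE 0.62, adjusted p 0.000987), SDG26 (AT1G76710) rose by 1.42 and JMJ13 (AT5G46910) fell by 1.15. Of 10 demethylase and methyltransferase genes 4 rose and 1 fell (4 and 2 adjusted over the list alone). That count of rises was 2 without the deeper NV library or either 40 d library. FPA (AT2G43410) fell by 0.63 (adjusted p 0.00551) in the autonomous pathway list, where 2 rose and 2 fell of 7 (2 and 2 adjusted over the list alone). Without the deeper NV or either 40 d library neither rise and only 1 fall was called. No gene of 6 in the FRI complex list was called by limma over all genes or adjusted over the list alone.

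Lists for cold, sugar and clock genes moved upward after 40 d. In cold acclimation 16 rose and 1 fell of 27 (16 and 1 adjusted over the list alone, 13 to 16 rises with 1 library left out), with a median log2 ratio of 1.51, at percentile 100 of random lists. For sugar and proline genes, 9 rose and 1 fell of 13 (10 and 1 adjusted over the list alone). The β-amylase BAM3 (AT4G17090) went from 13.6 to 138 (log2 change 3.38, SE 0.23, limma adjusted p 1.5e-06), and P5CS1 (AT2G39800) rose from 16.1 to 153. Proline dehydrogenase ERD5 (AT3G30775) fell from 275 to 15.1. Of 22 clock genes 18 rose and none fell (18 and 0 adjusted over the list alone, 16 or 17 rises with 1 library left out). CCA1 (AT2G46830) rose from 6.40 to 85.2 (3.79, SE 0.26, adjusted p 1.97e-06) and PRR9 (AT2G46790) rose by 3.08. The labels give no hour of harvest, which bounds what clock values can show.

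Flavonoid genes moved downward, with 10 falls and 2 rises of 15 (10 and 2 adjusted over the list alone), and 5 falls without the deeper 40 d library; no rise was called without the deeper NV library and 1 without the shallower NV or the deeper 40 d library. CHS (AT5G13930) fell from 283 to 43.2 (log2 change −2.75, SE 0.34, limma adjusted p 0.000109), DFR (AT5G42800) from 4.27 to 0.17 and LDOX (AT4G22880) from 2.74 to 0.131. In the light harvesting and Rubisco list 6 fell and 2 rose of 25 (6 and 2 adjusted over the list alone; 3 falls without either 40 d library, and 1 to 5 rises). RBCS3B (AT5G38410) fell from 809 to 37.8 and RBCS2B (AT5G38420) from 243 to 24.5, while LHCB1.1 (AT1G29920) rose by 1.87; reads of these paralogs were not separated further. Root markers had 8 falls of 14 (9 adjusted over the list alone, 6 to 8 with 1 library left out), among them EXPA7 (AT1G12560), which fell by 3.85, EXPA18 (AT1G62980), by 5.36, and CASP1 (AT2G36100), by 4.70. After 1 d of cold, 8 of these root markers had risen and none fallen (10 and 0 adjusted over the list alone, 4 rises without the deeper NV or the deeper 1 d library and 5 without the shallower 1 d library).

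The other lists after 40 d included heat shock, with a median log2 ratio of 1.09 (percentile 100 of random lists) inside its spread between libraries of 1.39, and jasmonate, with −1.31 (percentile 0, spread 0.85). Across these remaining lists, counts of 1 to 3 moved by up to 1 when a library was left out unless values stand beside them. Of 12 heat shock genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; 3 rises without the deeper NV or the deeper 40 d library), with HSFA7A (AT3G51910) up by log2 2.65 (limma adjusted p 0.00208). Of 15 gibberellin genes 5 fell (5 adjusted over the list alone; 3 without the deeper NV or the shallower 40 d library), GA2OX2 (AT1G30040) by 2.94. Jasmonate genes had 6 falls of 11 (7 falls and 1 rise adjusted over the list alone), but 2 without the deeper NV library, 0 without the deeper and 3 without the shallower 40 d library. For salicylic acid, 1 rose and 3 fell of 11 (2 and 3 adjusted over the list alone), PR5 (AT1G75040) up by 2.14 and EDS5 (AT4G39030) down, with a log2 change of −3.53. In the cell cycle list 1 rose and 2 fell of 24 (0 and 2 adjusted over the list alone): PCNA1 (AT1G07370), which fell by 1.33, and PCNA2 (AT2G29570), by 2.27. Senescence had 2 rises and 1 fall of 7 (2 and 1 adjusted over the list alone), with NAP (AT1G69490) up by 3.51. The meristem list had 1 rise of 4 (1 adjusted over the list alone; 0 without the deeper NV library), and the 1 measured floral organ gene, SEP4 (AT2G03710), was not called. Reference genes had 4 falls of 13 (4 adjusted over the list alone), but 2 without either NV library and 1 without either 40 d library; UBQ10 (AT4G05320) fell by 0.65.

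Shorter cold shows which of these changes were seen early. As the labels give no hour of harvest, what clock values can show is bounded at each of these times too. After 1 h, the clock gene PRR5 (AT5G24470) rose from 6.27 to 97.3 (log2 change 3.99, SE 0.36, limma adjusted p 0.00137), and kept the call without any library of either group. CBF2 (AT4G25470) had the largest ratio, 0.593 to 49.1, but its 2 libraries lay at 10.6 and 87.5 reads per M and limma did not call it (adjusted p 0.497). COR28 (AT4G33980) and FKF1 (AT1G68050) rose by 4.05 and 3.65, yet not without the deeper NV library (0.105 and 0.091) or the shallower one (0.162 and 0.16). limma called 15 rises and 1 fall after 1 h, 1503 genes having an unadjusted p under 0.05. With 1 library left out the rises ran from 2 to 256 and the falls from 0 to 68. The rises were 69 and 4 without the deeper and shallower NV library, 221 and 256 without the deeper and shallower 1 h library, and 2 to 7 without a library of 1 d, 10 d, 20 d or T10. Cold acclimation genes had 1 rise at that time, against 11 adjusted over the list alone, and 10 rises without the deeper 1 h library, 3 without the shallower, 0 without either NV library.

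After 1 d, COR15A had reached 366, ADH1 211, RD29A 329 and the clock gene RVE2 (AT5G37260) 92.9, from 0.693. The touch genes TCH4 (AT5G57560) and TCH3 (AT2G41100) fell from 133 to 1.95 and from 118 to 5.09, and asparagine synthetase ASN1 (AT3G47340) from 659 to 15.1. limma called 2588 rises and 2286 falls, with 19 rises and 1 fall among 27 cold acclimation genes (20 and 1 adjusted over the list alone). The rises were 1563 without the deeper NV library, 1307 and 1318 without the deeper and shallower 1 d library; the falls were 1425, 789 and 836. After 10 d, carbonic anhydrase CA1 (AT3G01500) fell from 561 to 9.48, with a log2 change of −5.82 (SE 0.30, adjusted p 3.8e-07), and RBCS3B by 5.71. FLC had not fallen by then, at 25 and 27.6 reads per M in the 10 d libraries. limma called 2480 rises and 2719 falls at 10 d, and 2591 and 2619 at 20 d. Without the deeper NV library the rises were 1636 and 1600. Without the deeper or shallower 10 d library there were 1216 or 1318 rises and 1240 or 1332 falls, and without the deeper or shallower 20 d library 1322 or 1259 rises and 1138 or 1141 falls.

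At T10, 10 d after the return to normal growth, FLC stayed below NV and SOC1 above it, while VIN3 had few reads. SVP, SWN, the starch genes SEX1 (AT1G10760) and BAM3, and clock genes were higher than in NV. LSU1 (AT3G49580), ATSDI1 (AT5G48850) and the β-glucosidase gene BGLU28 (AT2G44460) were among the largest rises. FLC was at 5.53, a log2 change of −1.57 from NV (SE 0.23, limma adjusted p 0.000603), and SOC1 at 12.2 (6.37, SE 0.87, adjusted p 0.000354). Against 40 d of cold, the further change of FLC was not called (−0.52, adjusted p 0.137). VIN3 had 20 and 0 reads at T10, and limma did not call it against NV (adjusted p 0.143).

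BGLU28 rose from 1.92 to 129 (log2 change 6.31, SE 0.44, limma adjusted p 3.94e-06), LSU1 from 3.84 to 101 and ATSDI1 from 8.38 to 165. HIS1-3 (AT2G18050), UGT74E2 (AT1G05680), UGT73C1 (AT2G36750), DOGT1 (AT2G36800), NUDT24 (AT5G19470) and PYD4 rose by 3.91 to 7.61. XTH4 (AT2G06850) fell from 206 to 26.7 (−2.93, SE 0.21, adjusted p 4e-06) and XTH18 from 35.1 to 2.69. The other falls at the top lost the call without the deeper T10 library, with log2 changes still from −5.57 to −2.74: ICL (AT3G21720), XTR6 (AT4G25810), AKN2 (AT4G39940), LRX3 (AT4G13340), ACS11 (AT4G08040), AGP12 (AT3G13520) and AT5G39580 then had adjusted p of 0.385, 0.314, 0.155, 0.147, 0.129, 0.0696 and 0.0534. ICL and XTR6 also lost the call without the deeper NV library (0.0678 and 0.0614), and ICL without the shallower T10 library (0.0559). The rRNA-like gene AT2G01021 had a mean of 7243 at T10 from 561 reads in the deeper and 83443 in the shallower library and was not called.

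limma called 2572 genes up and 2002 down at T10 against NV. Without the deeper T10 library, which leaves 1 library with 2.38 M reads in uniquely split genes, fewer genes were called in each direction. Of 125 called genes in lists or among the named ones, 50 kept the call without any library of either group. All 8 measured floral promotion genes, of 19 in the list, rose (8 adjusted over the list alone), but fewer rose with any library of either group left out. SOC1 and GI kept the call throughout. SVP rose from 17.5 to 74.4 (log2 change 2.11, SE 0.25, adjusted p 0.000167). SWN rose by 1.77 (adjusted p 0.000739), while CLF was not called (−0.23, adjusted p 0.662) and turned to 0.01 without the deeper T10 library. Of 22 clock genes 16 rose (16 rises and 1 fall adjusted over the list alone), 9 without the deeper T10 library. CCA1, PRR9, PRR7 (AT5G02810), PRR5 and FKF1 kept the call without any library. Of 13 sugar genes 8 rose, also with any library left out, SEX1 from 40.1 to 366 (3.23, SE 0.19, adjusted p 1.65e-06) and BAM3 from 13.6 to 140. In cold acclimation, 10 rose and 1 fell of 27 (10 and 1 adjusted over the list alone, 7 to 9 rises with 1 library left out), with COR15A still at 11.5 against 0.705 in NV. The chlorophyll b reductase NYC1 (AT4G13250) rose from 26.9 to 117 (2.12, SE 0.17, adjusted p 1.39e-05), and LOX2 (AT3G45140) by 2.19. EF1A (AT5G60390), a common reference gene, fell by 1.56, from 994 to 338. Root markers had 7 falls of 14 (7 adjusted over the list alone, none without the deeper T10 library), with a median log2 ratio of −0.94 at percentile 0 of random lists. In the cell cycle list the median was −0.58 (percentile 0.03, spread between libraries 0.55), with 1 fall of 24 (1 adjusted over the list alone), 0 without the deeper T10 and 5 without the deeper NV library.

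Between 40 d of cold and T10, KIN1, COR15A, ADH1, GOLS3, the lipid transfer genes EARLI1 (AT4G12480) and AZI1 (AT4G12470), and PORA fell. DR4 and DIN10, among the largest falls after 40 d, rose, as did MLP328 (AT2G01520), AOX1A (AT3G22370) and NUDT8 (AT5G47240). Flavonoid genes rose, and so did NYC1 and RBCS3B. Of 12 heat shock genes HSP23.6 (AT4G25200) rose and 2 fell, among them HSP101 (AT1G74310), which fell by 3.96 (1 and 4 adjusted over the list alone). The list had a median log2 ratio of −1.30 at percentile 0 of random lists and a spread between libraries of 1.16. Its falls were 0 without the deeper and 1 without the shallower T10 library, and 1 without the deeper and 6 without the shallower 40 d library, and its rises 2 without the deeper 40 d library. COR15A fell from 699 to 11.5 (log2 change −5.88, SE 0.27, limma adjusted p 1.16e-07). DIN10 rose from 6.32 to 431 (6.10, SE 0.29, adjusted p 1.37e-07) and AOX1A from 5.32 to 263 (5.62, SE 0.23, adjusted p 1.1e-07). AT4G23680 had no reads after 40 d and 858 and 170 at T10, at least 844-fold higher against a floor of 3 counts over the group. JMJ30 was left with 2 reads at T10, a ratio of 0.0178 to 40 d (0.00214 to 0.0649), CLF fell by 2.07 (adjusted p 0.000696) and VIN3 by 3.46 (adjusted p 0.0298). Without the deeper T10 library JMJ30, CLF and VIN3 lost the call (0.128, 0.106 and 0.163).

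Here limma called 2504 rises and 1890 falls. Without the deeper T10 library these were 1278 and 498, and without the deeper 40 d library 1331 and 1097. Of 115 called genes in lists or among the named ones, 65 kept the call without any library of either group. Flavonoid genes had 11 rises of 15 (11 adjusted over the list alone, 9 to 11 with 1 library left out): CHS rose from 43.2 to 293 (log2 change 2.83, SE 0.33, adjusted p 8.5e-05), DFR by 5.42 and LDOX by 5.32. UGT79B1 (AT5G54060), with no reads after 40 d, was at least 95.3-fold higher. Against NV, 5 flavonoid genes rose and none fell at T10 (8 and 0 adjusted over the list alone, 3 rises without the deeper T10 library), with a median log2 ratio of 0.65 at percentile 99.96 of random lists. CHS was not among them (0.08, adjusted p 0.896) and its sign turned without the shallower NV library (−0.16) or the shallower T10 library (−0.09). In cold acclimation 12 fell and 1 rose of 27 (12 and 1 adjusted over the list alone, 10 to 13 falls with 1 library left out). VSP1 (AT5G24780) rose from 0.112 to 14.4 among the jasmonate genes, where 4 rose of 11 (5 adjusted over the list alone).

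Of 1120 genes at least 2-fold higher after 40 d, 383 (34.2%) were so again at T10, and of 1754 lower ones 651 (37.1%). FLC, SOC1, COR15A, CCA1, BAM3, PYD4 and XTH18 are among the genes that limma called in the same direction both times. Independent lists of these sizes would share 89.0 and 136 genes, and simulated unchanged groups that share the NV libraries shared 3.18 and 1.22 on average of 100 draws, from lists of 25.8 and 30.9 higher and 25.9 and 36.9 lower genes, where independent lists would share 0.0425 and 0.0508. Shared controls alone thus raise the overlap above that of independent lists. How much of the excess at 40 d and T10 comes from the shared NV libraries was not measured, as these cannot be split with at least 2 in each set. By limma, 1114 of 3093 rises and 1080 of 3440 falls recurred (424 and 367 for independent lists). Among other RNA classes, 30 of 52 snoRNAs fell after 40 d and 12 at T10. In the deeper and shallower library, snoRNAs summed to 1135 and 1046 reads per M in NV, 143 and 122 at 40 d, and 254 and 84.6 at T10. They summed to 630 and 2188 at 1 h and 994 and 307 at 1 d, so their totals can differ widely within a group. Of 54 mitochondrial genes 21 fell at each of 40 d and T10, and 27 of 103 plastid genes rose and 8 fell after 40 d. Class counts were not repeated with a library left out. Uniquely split plastid genes summed to 79210 and 25050 reads per M in the NV libraries, on either side of the 40 d libraries (53021 and 55270). The deposited means of all 103 plastid genes, including those that could not be split, summed to 822919 in NV and 440003 after 40 d.

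H3K27me3 peaks numbered 5312 to 7800 per library and covered 8.21 to 17.44 Mb, H3K4me3 peaks 15848 to 16923 over 23.0 to 24.9 Mb, and H3K36me3 peaks 11990 to 12243 over 23.1 to 26.9 Mb. Exact permutation p for peak number or covered length between groups ran from 0.33, the smallest that 2 against 2 can give, to 1. Replicates 1 and 2 differ more than the groups do for H3K27me3: after 40 d replicate 1 covered 17.44 Mb and replicate 2 10.3 Mb. Gained and lost genes are therefore given beside the same counts for replicates 1 against replicates 2 and for the crossed pairs.

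H3K27me3 spread over FLC. Peaks covered none of the gene in NV, shares of 0.882 and 0.154 (replicates 1 and 2) after 40 d of cold, and 0.944 and 0.506 at T10, where FLC counted as gained. In the first T10 replicate 1 peak ran over chromosome 5 from 3173723 to 3179885. COR15A lost the mark, with shares of 0.613 and 0.554 in NV and 0 in the 4 later libraries, as did PHI-1 (AT1G35140). SWEET6 (AT1G66770) lost it after 40 d and had it again at T10, and CYP86A7 (AT1G63710) carried it at T10 alone (0.822 and 0.775). SOC1 kept H3K27me3 peaks in all 6 libraries.

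**Figure D2:**
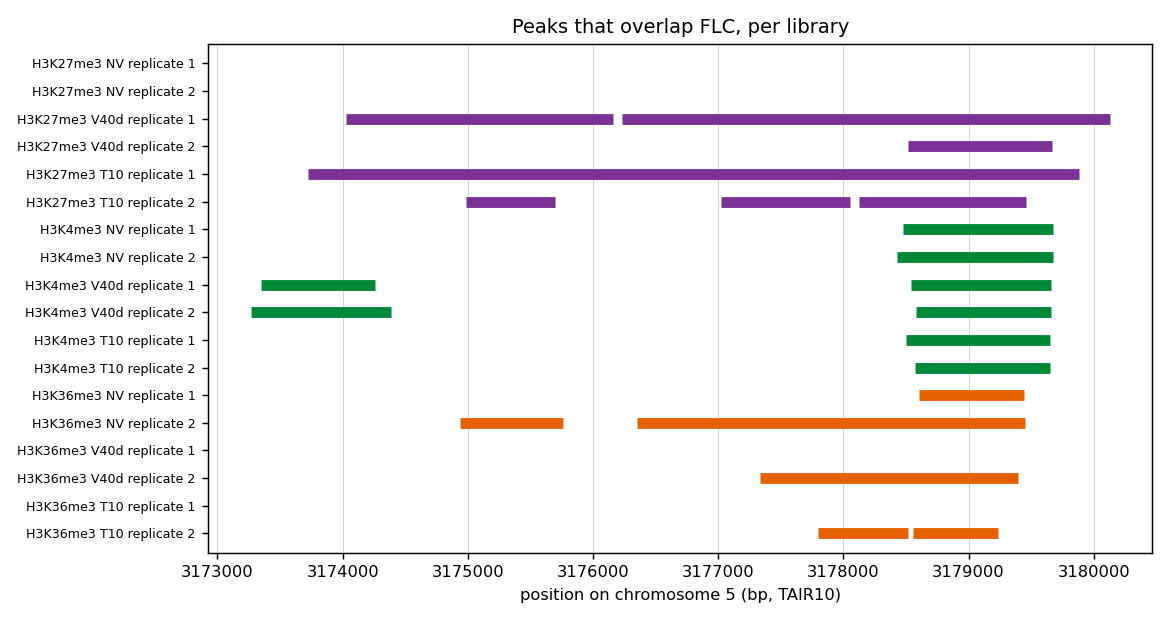
Peaks of the 3 marks over FLC on chromosome 5 of TAIR10, 1 line per library.

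After 40 d, 90 genes gained and 5 lost H3K27me3, against 739 and 28 for the replicate split and 49 and 0 for the crossed pairs; replicate 1 alone gave 1304 and 54, replicate 2 alone 465 and 248. At T10 against NV 134 gained and 5 lost it (662 and 28, 35 and 1; 1099 and 66 in replicate 1, 563 and 201 in replicate 2). From 40 d to T10 the counts were 13 and 6 (1299 and 24, 0 and 7; 175 and 392, 416 and 271). With the same covered length in each library, the split turned to 27 gained and 129 lost after 40 d, 31 and 77 at T10, and 27 and 16 from 40 d to T10. None of FLC, COR15A, PHI-1, SWEET6 and CYP86A7 was called under that setting. limma on the covered share called no gene of 5709 in any of the 3 comparisons, with 76, 100 and 18 genes at an unadjusted p under 0.05. Without replicate 2 at 40 d it called 245 higher and 3 lower after 40 d, and 2 higher and 216 lower from 40 d to T10. Of the 90 genes gained after 40 d, 52 were marked in both T10 libraries, 33 in 1 and 5 in neither.

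H3K4me3 came and went with the cold. DIN2 (AT3G60140), CCD7 (AT2G44990), COR15A, COR15B and KIN1 gained it after 40 d, from a share of 0 to 1 in both libraries, and DIN2, COR15A, COR15B and KIN1 had none left at T10. CA1 and the β-glucosidase PYK10 (AT3G09260) lost it after 40 d and had it back at T10, and so did LHCB1.2 (AT1G29910), LHCB1.4 (AT2G34430), LHCB2.3 (AT3G27690) and LHCB4.3 (AT2G40100). MAF5 (AT5G65080) gained it after 40 d (0.695 and 0.736) and kept it at T10 (0.663 and 0.707). At equal covered length the gains of CA1, PYK10 and LHCB2.3 from 40 d to T10 and of MAF5 at T10 against NV were not called. FLC kept its main peak in every library and had a second one after 40 d alone, over 3173347 to 3174258 and 3173267 to 3174387 (−log10 q 27.8 and 73.5).

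After 40 d, 216 genes gained and 410 lost H3K4me3 (355 and 25 in the replicate split, 8 and 14 in the crossed pairs; 523 and 937 in replicate 1 alone, 474 and 656 in replicate 2 alone). At T10 against NV 207 gained and 68 lost it (271 and 4, 14 and 7; 488 and 280, 682 and 191), and from 40 d to T10 565 and 160 (188 and 4, 18 and 11; 1011 and 389, 989 and 316). With equal covered length these were 276 and 296, 92 and 196, and 236 and 349, so the balance of gains and losses turned at T10. Of the 216 genes gained, 62 were marked in both T10 libraries and 123 in neither; of the 410 lost, 331 were marked again in both. limma called 211 higher and 421 lower of 5183 after 40 d, 157 and 55 at T10, and 483 and 160 from 40 d to T10. At equal covered length these were 239 and 254, 66 and 135, and 199 and 254, so the balance turned in both T10 comparisons. The higher count after 40 d was 396 without replicate 2 at 40 d. At T10 it was 298 without NV replicate 1 and 262 without T10 replicate 2, and the lower count was 202 without NV replicate 2 and 93 without T10 replicate 1. From 40 d to T10 the lower count was 323 without replicate 2 at 40 d.

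**Figure D3:**
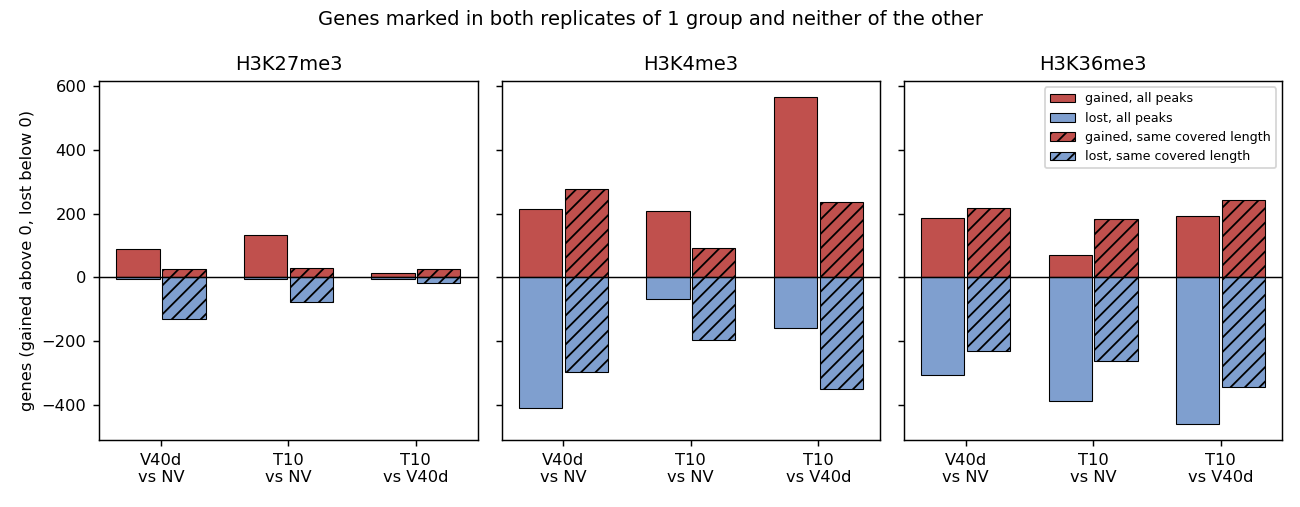
Genes that gained or lost each mark, from all peaks and with the same covered length in each library of a mark.

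H3K36me3 appeared over AT3G55580, COR413IM1 and AT1G70630 after 40 d, with none in NV. SNC1 (AT4G16890), RPP5 (AT4G16950), FPA and BAM3 lost it. SNC1, FPA and RPP5 regained coverage by T10 while BAM3 did not (0.685 and 0.721 in NV, 0 and 0 after 40 d, 0 and 0.13 at T10). NAC046 (AT3G04060) carried the mark at T10 alone (0.747 and 0.749), and TRM6 (AT3G05750) lost it by then. The calls of AT3G55580, BAM3, NAC046 and TRM6 ended at equal covered length. On FLC the covered share was 0.139 and 0.648 in NV, 0 and 0.339 after 40 d, and 0 and 0.231 at T10.

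After 40 d, 186 genes gained and 307 lost H3K36me3 (31 and 306 in the replicate split, 28 and 20 in the crossed pairs; 604 and 767 in replicate 1 alone, 452 and 656 in replicate 2 alone). At T10 against NV the counts were 71 and 389 (27 and 337, 13 and 8; 256 and 1396, 211 and 875), and from 40 d to T10 192 and 460 (29 and 329, 11 and 24; 481 and 1458, 450 and 910). With equal covered length they were 217 and 230, 182 and 263, and 242 and 344. Filtered tags and covered length were lower at T10 than in NV within each replicate number (15.3 and 8.49 M tags, 25.1 and 23.1 Mb in replicate 1; 23.3 and 16.7 M, 26.9 and 25.3 Mb in replicate 2). limma called 39 higher and 96 lower of 8253 after 40 d, 58 and 110 at T10, and 103 and 101 from 40 d to T10. At equal covered length its balance turned against NV, to 89 and 58 after 40 d and 141 and 5 at T10, with 129 and 23 from 40 d to T10. Regions merged from all peaks turned too, from 74 gained and 183 lost to 170 and 70 after 40 d, from 93 and 221 to 272 and 20 at T10, and from 146 and 183 to 232 and 48 from 40 d to T10. Without NV replicate 1 or 2 it called none at T10 against NV, where 808 and 645 genes had an unadjusted p under 0.05. After 40 d the higher count was 8 and 12 without NV replicate 1 and 2 and 9 without replicate 2 at 40 d. The lower count was then 49 and 42 without NV replicate 1 and 2, and 30 and 9 without replicate 1 and 2 at 40 d. At T10 the higher count was 88 without T10 replicate 2 and 35 without either 40 d replicate, and the lower count was 48 without T10 replicate 1. From 40 d to T10 the higher count was 65 without either NV replicate, 53 and 59 without replicate 1 and 2 at 40 d; the lower count was 54 without either NV replicate and 37 without T10 replicate 1.

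The marks were set beside RNA to ask whether transcripts moved with them. Genes that gained H3K4me3 after 40 d had a median log2 RNA ratio of 0.23 (141 genes, percentile 100 of matched random sets, and 0.10 at equal covered length) and those that lost it −0.40 (323 genes, percentile 0), with 132 of these falling and 36 rising. CA1 fell from 561 to 47.4 and PYK10 from 1477 to 422 as they lost the mark. DIN2 rose from 10.6 to 55.7 as it gained the mark, and on to 131 at T10 without it. GLYI4 (AT1G15380) gained the mark after 40 d and yet went from 20.8 to 4.91 (limma adjusted p 0.012), a call lost without the deeper NV library (0.103) or either 40 d library (0.0804 and 0.0541). Genes that gained H3K36me3 after 40 d had a median of 0.28 (171 genes, percentile 100), and those that lost it 0.02 (293 genes, percentile 61.5). BAM3 transcripts rose while H3K36me3 over the gene was lost, a loss not called at equal covered length. Genes that gained H3K27me3 had a median of −0.62 after 40 d (28 genes, percentile 0.05) and −0.32 at T10 (36 genes, percentile 1.17). With a covered share of 0.8 these were −0.39 (22 genes, percentile 3) and −0.28 (29 genes, percentile 4.24), less extreme among random sets. At equal covered length the set after 40 d lay at percentile 0.48 (11 genes). JAL34 (AT3G16460) gained H3K27me3 after 40 d and fell from 399 to 104, and TIP2;3 (AT5G47450) fell from 5.01 to 0.214, while FRD3 (AT3G08040) rose from 1.07 to 13 despite the gain. FUT5 (AT2G15370), also a gain, had a ratio of pooled reads of 0.00711 (0.000178 to 0.0404). MYB12 (AT2G47460) rose by log2 2.29 at T10 (limma adjusted p 0.001) while it gained the mark. Of JAL34, TIP2;3, FRD3, FUT5 and MYB12, FRD3 alone kept its gain at equal covered length.

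At T10 against NV, genes that gained or lost H3K4me3 had medians of 0.13 (142 genes, percentile 99.6) and −0.39 (54 genes, percentile 0.01), and for H3K36me3 0.18 (68 genes, percentile 97.9) and −0.05 (379 genes, percentile 11.9). At equal covered length the median for gained H3K4me3 was 0.014 (72 genes, percentile 71.6). AT3G46280 gained H3K4me3 at T10, though not at equal covered length, while it fell from 33.4 to 4.28 (limma adjusted p 0.000109). With equal covered length, genes that lost H3K27me3 after 40 d had a median of −0.52 (45 genes, percentile 0.01), so gains and losses of that mark lay on the same side there. At T10 against NV they lay on opposite sides under that setting. The medians were −0.45 for gained (10 genes, percentile 3.84) and 0.18 for lost H3K27me3 (26 genes, percentile 93.5). No overlap of genes gaining or losing different marks passed the threshold in 36 Fisher tests. Many expected overlaps were small, such as 0.0394 genes with lost H3K27me3 and gained H3K4me3 after 40 d. A test without a call says little there. The smallest adjusted p was 0.262, for genes that gained H3K4me3 and lost H3K36me3 from 40 d to T10, 2 genes against 9.47 for independent sets.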

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

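All tests that weigh an explanation in this part were chosen after the result was seen, and the RNA test behind the flavonoid and senescence counts was added after the data were seen. Peaks were called on the plastid genome, which carries no histones and stands outside the comparisons, in 4 of 6 H3K27me3 libraries: 17 and 18 in NV replicates 1 and 2, 19 in replicate 2 at 40 d of cold and 23 in T10 replicate 2. On the mitochondrial genome there were 5 in NV replicate 2 and 13 in T10 replicate 2. Replicate 1 at 40 d and at T10 had none on either genome, NV replicate 1 had 0 and replicate 2 at 40 d had 1 on the mitochondrial genome. H3K4me3 libraries had none on either, and of the H3K36me3 libraries T10 replicate 1 had 3 on the plastid genome and the others none.

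In 2 fixed lists at least 50% of the measured members changed one way between 40 d and T10, by a test of that difference itself, the limma contrast of T10 with 40 d. Of 15 flavonoid and anthocyanin genes, 11 rose and none fell, and 9 to 11 rose with 1 library left out. Of 7 senescence genes 4 rose and 1 fell, but 1 rose without the deeper T10 library and 2 without the deeper 40 d library. Cold acclimation (12 falls of 27) and the clock (7 falls of 22) stayed below that share.

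More genes gained than lost H3K27me3 at 40 d (94.7% of calls) and at T10 against NV (96.4%). With the same covered length in each library gains made up 17.3% and 28.7%, but that setting removes a net gain whatever its cause, so different amounts of sequence called between libraries cannot be told apart from the cold treatment. Covered length was higher than in NV within each replicate number, 12.1 Mb in NV, 17.44 at 40 d and 16.6 at T10 in replicate 1, and 8.21, 10.3 and 9.27 in replicate 2. Filtered tags were higher as well, 6.01, 15.6 and 12.1 M in replicate 1 and 3.42, 3.86 and 6.60 M in replicate 2, M being 1e+06, so depth goes with the groups. At 40 d, limma on the covered share called 0 genes in the gained direction (76 at an unadjusted p under 0.05, 241 with the replicate number as a block). With 2 libraries per group this leaves small and large changes open. AT3G56230 went from shares of 0.331 and 0 in NV to 1 and 0.886 at 40 d without a call by limma.

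From 40 d to T10, more genes gained than lost H3K4me3 (77.9% of calls). At equal covered length gains made up 40.3%, which for the same reason does not separate different amounts of sequence called from a change after the return to warmth. Filtered tags went from 33.8 to 37.0 M in replicate 1 and from 23.9 to 30.6 M in replicate 2, and covered length from 24.2 to 24.9 and from 23.0 to 23.9 Mb.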

How the results depend on the processing

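The RNA test with its alternatives, the merged regions and the equal covered length for the RNA of marked genes were chosen after the data were seen, the other alternatives before. The cause was not tested for any change given here, beyond what a setting does by construction, such as fitting fewer libraries or keeping fewer peaks. A count is given as moved where it lies outside 1.5 times the reported count. Comparisons stand in the order 40 d of cold against NV, T10 against NV and T10 against 40 d unless named. Depth limits the RNA values most at T10, where the shallower library holds 2.38 M reads in uniquely split genes, M being 1e+06. Depth limits H3K27me3 too, with 3.42 to 15.6 M tags per library. Every ChIP-seq call compares 2 libraries with 2, and peak files give no value where nothing was called. Both replicates and all marks of a time point were called against the same input library. It held 19.5 M filtered tags in NV, 20.6 M at 40 d and 12.2 M at T10. An effect of the input thus cannot be told apart from the group. The simulated RNA changes of 2-fold were found in 41% of cases, so a gene without a call can still have changed by that much.

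RNA calls by size depend on the pseudocount, which by construction pulls the ratios of weakly expressed genes toward 0. At a pseudocount of 5, higher and lower genes were 80 and 8 (1 h), 491 and 475 (1 d), 397 and 672 (10 d), 399 and 665 (20 d), 462 and 713 (40 d), 648 and 552 (T10 against NV) and 781 and 470 (T10 against 40 d). The reported counts, at a pseudocount of 1, were 188 and 19, 1095 and 1205, 913 and 1607, 964 and 1576, 1120 and 1754, 1493 and 1459, and 1697 and 1202. At a pseudocount of 0.1, moved counts were 369 higher and 102 lower at 1 h, 1668 and 1842 at 1 d, 1388 higher at 10 d, 1546 at 20 d and 1706 at 40 d, and 2220 lower at T10 against NV and 1859 against 40 d. The other 5 counts stayed within 1.5 times. Having no floor left all 14 counts identical, because a 2-fold ratio at pseudocount 1 already needs a value of 1 or more, so it says nothing about stability. A floor 5 times higher moved none of 16 counts, including those of genes called both at 40 d and T10, and neither did median-ratio scaling.

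Of 69 list medians, 43 stayed within their spread at a pseudocount of 5 and 65 under median-ratio scaling over nuclear genes. At a pseudocount of 5 the FLC clade had medians of 0.30 at 40 d and −0.35 from 40 d to T10, and floral promotion 0.17, 0.34 and 0.19. Autonomous pathway had 0.13 at 40 d, cold acclimation 0.38 at T10 against NV and −0.25 against 40 d, and the sugar list −0.25 against 40 d. The circadian clock had 1.00 at 40 d and −0.24 from 40 d to T10, flavonoid synthesis −0.56, 0.35 and 0.72, and gibberellin −0.0805 and −0.0455 against NV. From 40 d to T10 jasmonate had 0.47 and the cell cycle −0.22. Floral organ identity had 0.18, 0.31 and 0.14, meristem genes 0.13 at 40 d and −0.18 from 40 d to T10, and root markers −0.44, −0.45 and 0.062. None of these moved medians changed sign. Under median-ratio scaling the sugar list had −0.38 from 40 d to T10 and floral organ identity 0.38, 0.67 and 0.29. That scaling shifted log2 ratios against NV by −0.03 at 40 d.

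For the RNA test, limma-trend moved 1 of 14 counts, the rises at 1 h, to 24 from 15, and a filter at 1 read per M in at least 2 libraries moved none. With 1 library left out, the lone library of its group is assumed to vary like the other groups. Rises and falls then ran from 2 to 256 and 0 to 68 at 1 h, 1307 to 3261 and 789 to 3052 at 1 d, 1216 to 3202 and 1240 to 3463 at 10 d, and 1259 to 3332 and 1138 to 3444 at 20 d. At 40 d they ran from 1878 to 3762 and 1865 to 4188, at T10 against NV from 1109 to 3230 and 373 to 2849, and against 40 d from 1278 to 3140 and 498 to 2516. The highest counts came without a 1 h library, whose within-group correlation was the lowest. Among 117 values of named genes, limma-trend left 108 on their side of the threshold, added 6 calls and ended 3. Without the deeper NV library 84 kept their side and 9 calls ended. Without the shallower NV library 82 kept it, 6 calls were added and 4 ended. Without the deeper T10 library 48 kept it, 2 were added and 14 ended, and without the shallower one 58 kept it and 4 ended. Without the deeper 40 d library 59 kept it and 5 ended, and without the shallower one 58 kept it, 1 was added and 5 ended. Without the deeper 1 h library 9 kept it and 3 were added, and without the shallower one all 12 kept it. Signs turned for values that had not been called. The log2 change of CHS at T10 against NV ran from −0.16 without the shallower NV library to 0.29 without the deeper one, with −0.09 without the shallower T10 library. That of CLF ran from −0.46 without the deeper NV library to 0.011 without the deeper T10 library. AT2G01021 without the shallower T10 library was at −3.41 against NV and −1.35 against 40 d, and without the deeper T10 library it was called at 6.27 and 8.33.

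Of 66 ChIP-seq values, 42 moved with the same covered length in each library of a mark, a setting that by construction removes a net gain or loss of marked sequence. Genes that gained and lost H3K27me3 were then 27 and 129, 31 and 77, and 27 and 16, against reported counts of 90 and 5, 134 and 5, and 13 and 6. For H3K4me3 they were 92 and 196 at T10 against NV and 236 and 349 against 40 d, and 182 genes gained H3K36me3 at T10 against NV. For H3K4me3, limma called 254 lower at 40 d, 66 higher and 135 lower at T10 against NV, and 199 higher and 254 lower against 40 d. For H3K36me3 it called 89 higher and 58 lower at 40 d, 141 and 5 at T10 against NV, and 23 lower against 40 d. Merged regions, which use no gene table, moved too. For H3K27me3 they were 36 gained and 183 lost (from 126 and 11), 34 and 109 (from 211 and 11), and 20 lost against 40 d (from 6). For H3K4me3 they were 77 and 193 at T10 against NV (from 222 and 65) and 244 and 392 against 40 d (from 613 and 212). For H3K36me3 they were 170 and 70 (from 74 and 183), 272 and 20 (from 93 and 221), and 232 and 48 (from 146 and 183). RNA medians at 40 d under equal length were −0.73 for gained H3K27me3, 0.10 and −0.44 for gained and lost H3K4me3, and 0.23 for gained H3K36me3. For T10 against NV these medians were 0.18 for lost H3K27me3, from 1.65, and 0.014 for gained H3K4me3. The other 24 values under that setting did not move.

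With a covered share of 0.8, 3 genes lost H3K27me3 at 40 d and 12 from 40 d to T10. H3K36me3 was gained and lost by 102 and 170, 29 and 132, and 102 and 182 genes. RNA medians at 40 d were then −0.39 and 5.28 for gained and lost H3K27me3, the latter from −0.46 and resting on at most 3 genes. They were −0.29 for lost H3K4me3, and 0.17 and −0.11 for gained and lost H3K36me3. At T10 against NV they were 0.081 and −0.48 for gained and lost H3K4me3 and 0.021 for gained H3K36me3. The other 50 values did not move. For the 36 overlaps between marks among them, this means only that no Fisher test passed under either setting. Some of their counts changed: genes that lost both H3K4me3 and H3K36me3 at 40 d went from 7 to 3. Genes that gained both H3K27me3 and H3K4me3 at T10 against NV went from 0 to 3. A count also says nothing of its members. Of 105 genes that gained H3K27me3 at 40 d and 132 at T10 against NV with a share of 0.8, 21 and 26 were among the reported ones. With any overlap of 1 bp, 59 genes gained and 8 lost H3K27me3 and 66 gained and 179 lost H3K36me3 at 40 d, 222 lost H3K36me3 at T10 against NV and 159 against 40 d, while 12 counts did not move. With −log10 q of at least 10, 2 genes lost H3K27me3 and 109 lost H3K4me3 at T10 against NV, where limma called 83 lower for H3K4me3, and 33 counts did not move.

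Within a single replicate number every gained and lost count was over 1.5 times the pooled one, since a call then needs 1 library per group. H3K27me3 gains and losses ran from 465 to 1304 and 54 to 248, 563 to 1099 and 66 to 201, and 175 to 416 and 271 to 392. For H3K4me3 they were 474 to 523 and 656 to 937, 488 to 682 and 191 to 280, and 989 to 1011 and 316 to 389. For H3K36me3 they were 452 to 604 and 656 to 767, 211 to 256 and 875 to 1396, and 450 to 481 and 910 to 1458. With each library left out of limma, higher and lower genes for H3K27me3 ran from 0 to 245 and 0 to 3 at 40 d and from 0 to 2 and 0 to 216 from 40 d to T10. Against NV, T10 stayed at 0 in each direction, with 127 to 225 genes at an unadjusted p under 0.05. For H3K4me3, higher genes ran from 214 to 396 at 40 d, higher and lower from 161 to 298 and 49 to 202 at T10 against NV, and lower from 154 to 323 against 40 d. For H3K36me3 they ran from 8 to 34 and 9 to 95, 0 to 88 and 0 to 111, and 53 to 126 and 37 to 113.

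The labels give the ChIP-seq replicates a number and name no shared batch or day, though files of one number were processed alike. Deviations of libraries with the same number from their group means correlated at 0.202 to 0.58, with 2 pairs per comparison. With the replicate number as a block, limma called no gene for H3K27me3 (241, 287 and 44 genes at an unadjusted p under 0.05). It called 195 higher and 400 lower, 138 and 49, and 464 and 152 for H3K4me3, and 40 and 102, 57 and 99, and 103 and 104 for H3K36me3. The block moved none of these 18 counts by over 1.5 times. No paired analysis was possible for RNA because the averaged columns carry no replicate number. The libraries are not independent of such a structure: NV and 1 h libraries correlated across the groups at 0.973 (deeper NV, shallower 1 h) and 0.97 (shallower NV, deeper 1 h), above 0.952 within NV and 0.925 within 1 h. What these libraries share is not known, so the counts at 1 h, from an unpaired fit, are bounded by it.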

Other observations

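Values at shorter cold are given here without a test against 40 d. The Rubisco genes RBCS2B (AT5G38420) and RBCS3B (AT5G38410) had their lowest means at 10 d: RBCS2B went from 243 in NV to 7.57 at 10 d and 14.4 at 20 d (log2 change −4.99 at 10 d, limma adjusted p 9.02e-08), and stood at 24.5 at 40 d. In their list of 25 genes, 11 fell and 1 rose at 10 d (15 and 1 adjusted over the list alone), and 7 fell without either 10 d library. LHCB1.1 (AT1G29920), an antenna gene, rose from 1573 to 4164 at 10 d and 5442 at 20 d. The chaperone HSP70 (AT3G12580) fell from 72.4 to 1.66 at 10 d (−5.34, adjusted p 0.00112), where 3 of 12 heat shock genes fell (3 adjusted over the list alone), 6 without the shallower NV library and 1 without either 10 d library. Clock genes had risen by 1 d, 16 of 22 with 1 fall (18 and 1 adjusted over the list alone, 11 to 16 rises with 1 library left out): CCA1 from 6.40 to 101, RVE1 (AT5G17300) from 4.63 to 98.4 and TOC1 (AT5G61380) from 14.3 to 61.1. That fall was not called without the deeper NV or either 1 d library.

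The tests on root markers given here were chosen after their values were seen. After 40 d of cold, 14 measured root markers had a median fitted log2 change of −1.66. Less root tissue in the sampled seedlings would lower every marker by about the same factor, but 6 of the 14 lay over 2 standard errors above that median and 6 as far below it, which argues against it as the whole cause. Among those above, the iron transporter IRT1 (AT4G19690) went from 50.6 to 91.4 (log2 change 1.38, limma adjusted p 0.189), and among those below LRX1 (AT1G12040) went from 2.15 to 0.0244. A candidate explanation is a lower shared level in root hair cells: the 6 root hair markers had a median of −4.61 and the other 8 markers −0.31 (with CASP1 (AT2G36100), an endodermis marker among these 8, at −4.70), a difference of −4.3 where 3003 exchanges of the markers gave a 5th percentile of −3.50. As the split was drawn after the values were seen, the test cannot decide it, and fewer root hairs were not tested apart from lower transcript levels within them.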
